A study of Homo sapiens with 11 samples.

How the data were processed

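The study mapped binding sites of estrogen receptor alpha (ERα) in MCF7 cells, an estrogen receptor-positive human breast cancer cell line. Per the labels' protocols, cells were kept for 72 h in medium with 10% charcoal-stripped serum, which removes steroid hormones, and then exposed to a compound or to the vehicle DMSO for 45 min. Chromatin was crosslinked with 1% formaldehyde for 15 min, sheared to 300 to 500 bp and immunoprecipitated with an antibody against ERα. Libraries were sequenced as 75 nt single-end reads. Material from 2 plates was pooled for each treatment before analysis, so each of the 10 treatments had 1 ChIP library. A pooled input sample had no list of its own and was not analysed here.

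The treatments were DMSO, E2 (estradiol, the natural agonist), Tamoxifen (a selective estrogen receptor modulator, listed in the design text as its active metabolite 4-OHT), Fulvestrant (a receptor antagonist and degrader), Rad1901, 800, H3B-5942, Saturated H3B-5942, H3B-6545 and Saturated H3B-6545. The labels gave no dose and did not say what 800 or saturated stands for. Groups were taken from the treatment label of each sample.

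Reads were aligned with BWA (version not given in the sources used here) to the human genome build hg19 and peaks were called with MACS2 2.1.1.20160309, per the submitters' processing notes. The deposited file of each library was a list of peak summits, 1 bp each, with a score per summit. The deposited score was read as the −log10 of a p or q value, as MACS2 writes it; which of these it was, and which control was used in the calling, are not given in the sources used here. The lowest score of each list lay between 2.00 and 2.11, next to the value of 2 that a threshold of 0.01 gives. The score is the authors' own value for a summit. It depends on the depth of its library, so it was used only to rank, filter or describe summits within a list, and ranks from lists of different lengths show no change.

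Peaks were called per library. Read totals are not in the lists, so the depth of each library is unknown. A longer list can come from a deeper library or a better enrichment as well as from the treatment, and with 1 library per treatment these were not separated by any replicate. No test across samples was run and no p-value is given. Shares have exact Clopper-Pearson 95% intervals and numbers of sites have exact Poisson 95% intervals. These intervals cover counting error only, and not the variation between cultures or libraries. Neighbouring summits are not fully independent, so the intervals are if anything too narrow.

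Summits of different lists were matched when they lay within 200 bp. Chance matching was measured by shifting the second list by 10 fixed distances from 20 to 100 kb. To remove the bound that list length sets on an overlap, lists were also compared at equal length. This kept the 7377 highest-scoring summits of each, which is the length of the DMSO list. The DMSO list was thus kept whole, down to a score of 2.00. The lowest score kept was 7.70 for Tamoxifen, 10.6 for H3B-5942, 15.3 for Fulvestrant and 15.5 for E2. Equal length therefore sets the weakest DMSO calls beside lists that lost theirs. Union sites were made by joining summits of all lists that lay within 200 bp of a neighbour. They had a median width of 50 bp and a largest width of 800 bp. Matched shares of related compounds over the same sites were compared by their difference, with an exact binomial interval conditional on the sites matched in 1 list of the pair and not the other.

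The genes named were fixed as 5 lists before the data were examined: 30 estrogen target genes, 10 luminal factors, 6 basal or mesenchymal genes, 12 genes of other lineages and 6 housekeeping genes. For each gene, summits in the gene body or within 50 kb of it were counted. No hg19 annotation was used here. The gene positions were written by hand from general knowledge of hg19, rounded to 1 kb, before the data were examined. All 64 genes lay on the same chromosome in a GRCh38.p14 gene table, and for 61 of the 64 the start and the end were offset alike, within 20 kb, between the hand-written positions and that table. This checks the chromosome and the length of a gene, and does not bound the error of its position. A summit in such a window is near the gene and is not shown to regulate it. The windows of TFF1 and TFF3, of KRT8 and KRT18, of RARA and IGFBP4, and of KRT13 and KRT14 overlap, so 1 summit can count for both genes of a pair. The same rule also named the 3 highest-scoring summits of each list and, in each direction of a main comparison, the 5 highest-scoring summits with no summit of the other list within 1000 bp; these are given by position, all 5 for the comparisons with E2 and the highest in each direction within the H3B pairs. Positions are 1-based in hg19.

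The matching was tested on simulated lists made from the E2 list of 17458 summits and the H3B-6545 list of 16426 summits. With true shares of 30, 60 and 90%, the mean recovered share differed from the true one by at most 0.0585 percentage points, and at least 92 of 100 intervals covered it. All 200 sites planted in 1 of 3 copies of the E2 list were recovered as list-only sites. Simulated summits were kept independently, moved by less than the match distance, and the added ones lay far from all others. The simulation therefore checks the calculation, and not how well real, clustered summits are matched. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

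The alternatives tried were match distances of 100 and 500 bp, a score of at least 10, lists of equal length, equal-length lists of 2000 and 5000 summits, gene windows of 20 and 100 kb, chromosomes 1 to 22 and X only, and summits of 1 peak counted once. Removal of the 5 bins of 50 kb whose summit number differed most between lists was added after the lists were seen. The share of summits with a sequence motif, the place of summits relative to transcription start sites, and the percentile of each gene list among random lists were planned and not run, because they need a sequence or annotation of hg19.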

Results

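ERα binding was profiled by ChIP-seq in hormone-deprived MCF7 cells after 45 min with vehicle or 1 of 9 treatments, with 1 library each. The deposited lists held 7377 summits for DMSO, 17458 for E2, 11001 for Tamoxifen and 19247 for Fulvestrant. There were 15315 for Rad1901, 15195 for 800, 14550 for H3B-5942, 13614 for Saturated H3B-5942, 16426 for H3B-6545 and 14540 for Saturated H3B-6545. The depth of the libraries is unknown, and no difference between treatments has a replicate check.

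**Figure D1:**
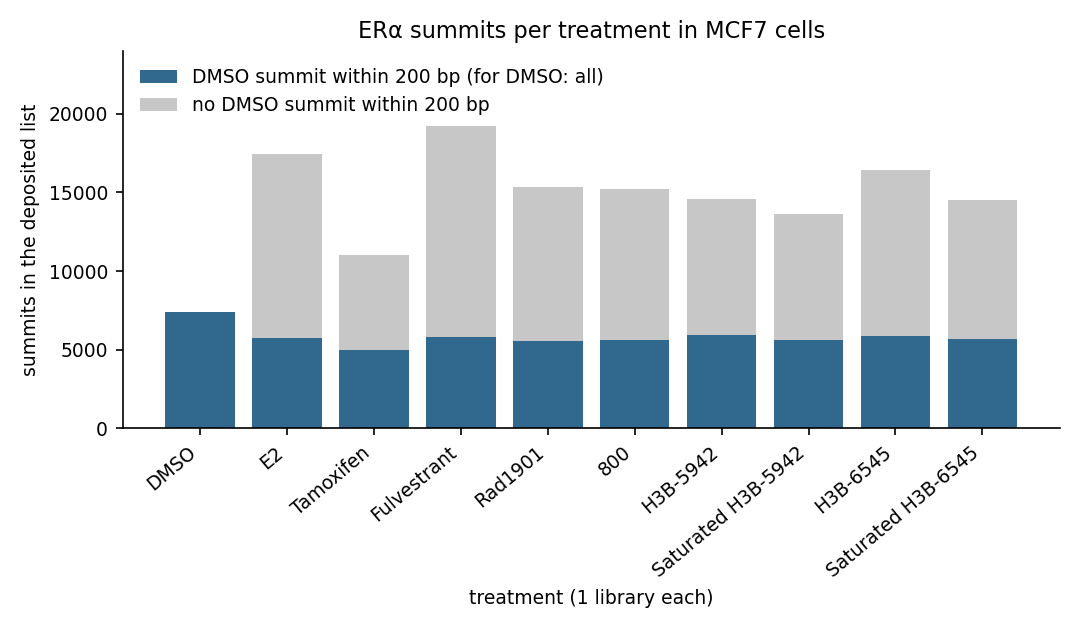
Bars give the number of ERα summits (vertical axis) in the list of each treatment (horizontal axis, 1 library each), split into summits with a DMSO summit within 200 bp (blue) and without (grey). DMSO had 7377 summits, and the treated lists ran from 11001 for Tamoxifen to 19247 for Fulvestrant.

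The comparison of E2 with DMSO asked where the receptor was found with its natural ligand and with vehicle. Of the 30 estrogen target genes, 29 had at least 1 E2 summit (96.7%, 95% interval 82.8 to 99.9) and 26 had a DMSO summit (86.7%, 69.3 to 96.2). The E2 list had more summits than the DMSO list at 27 of these genes and fewer at 0. GREB1, an early estrogen-induced gene of breast cancer cells, had 15 E2 and 6 DMSO summits, and IGF1R, the receptor of insulin-like growth factors, had 22 and 5. The nuclear receptor corepressor gene NRIP1 had 4 and 0, the secreted glycoprotein gene STC2 had 6 and 0, and the transcription factor genes MYC and EGR3 each had 5 and 1. Several of these numbers depended on the length of the list: with the 7377 highest-scoring summits of each list (equal length), E2 and DMSO had 7 and 6 at GREB1, 4 and 5 at IGF1R, 0 and 0 at STC2 and 0 and 1 at MYC. NRIP1 then had 3 and 0, and EGR3 had 3 and 1.

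The number of summits in all 30 windows was 196 for E2 and 82 for DMSO. Per 1000 summits of the list this came to 11.2 (9.72 to 12.9) for E2 and 11.1 (8.85 to 13.8) for DMSO. The E2 list as a whole was 2.37 times as long as the DMSO list. At equal length the windows held 12.5 summits per 1000 (10.1 to 15.3) in the E2 list, and E2 had more summits than DMSO at 13 of the 30 genes, fewer at 7 and as many at 10.

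The trefoil factor gene TFF1 and GREB1 held sites that were present in all 10 lists, DMSO included. A TFF1 site at chromosome 21, 43796583 to 43796615, ranked 48 of 17458 by score in the E2 list and 108 of 7377 in the DMSO list. A site at 43786789 to 43786913 ranked 288 in the E2 list and 1078 in the DMSO list. A GREB1 site at chromosome 2, 11638849 to 11638873, ranked 35 in the E2 list and 63 in the DMSO list. Among the GREB1 sites held by at least 2 lists, 7 were present in the E2 list and absent from the DMSO list. The 3 of them at 11646401 to 11646449, 11652837 to 11653024 and 11675991 to 11676334 are named because they were in every list but DMSO and Fulvestrant, a choice made after the values were seen.

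**Figure D2:**
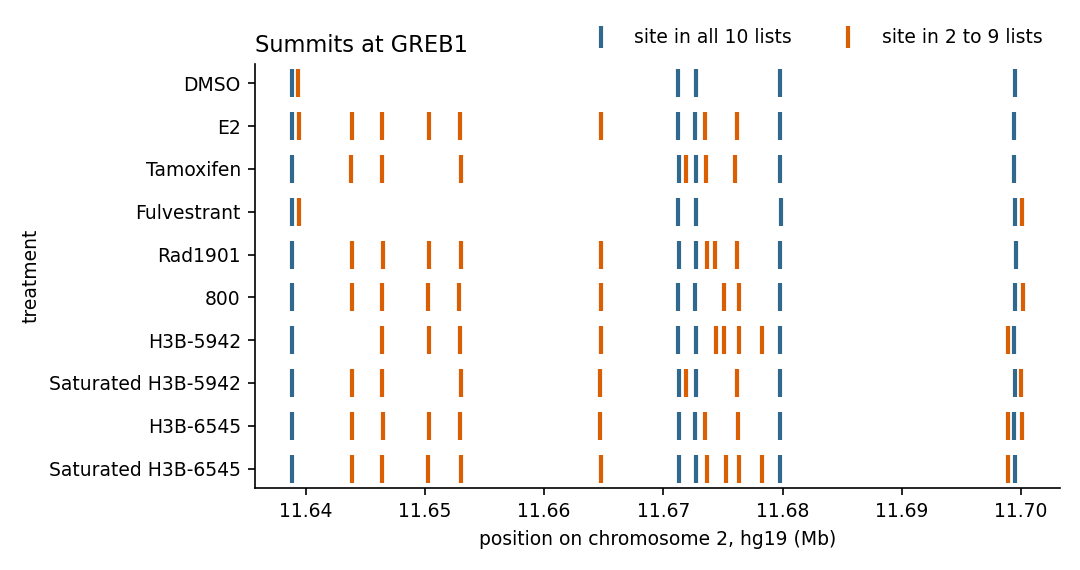
Ticks mark ERα summits at GREB1 by position on chromosome 2 in hg19 (horizontal axis, Mb) in the list of each treatment (vertical axis), for sites present in at least 2 lists. The 5 sites in blue were in all 10 lists, and sites in orange were in 2 to 9 lists; of the 14 orange sites, DMSO lacked 13, Fulvestrant 12, Tamoxifen 8 and each of the other lists 4 to 7.

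Of the 17458 E2 summits, 32.9% (32.2 to 33.6) had a DMSO summit within 200 bp, and 11712 had none. Shifted DMSO lists matched at most 0.430%. Of the 7377 DMSO summits, 77.9% (76.9 to 78.8) had an E2 summit. Within the E2 list, the median score was 35.2 for summits with a DMSO match and 9.39 for those without. Among the 1000 highest-scoring E2 summits, 97.6% (96.4 to 98.5) had a DMSO summit within 1000 bp; over all pairs of lists this share was 95.5% or more. The highest-scoring E2 summits with no DMSO summit within 1000 bp were at chromosome 19, 1513389 (rank 121), chromosome 1, 202082172 (rank 166), chromosome 9, 130789349 (rank 188), chromosome 19, 2576346 (rank 315), and chromosome 10, 65390541 (rank 331). Each of these 5 sites was present in all 9 treated lists. In the other direction, the highest-scoring DMSO summit with no E2 summit was at chromosome 19, 42748949, rank 153 of the DMSO list, and this site was in 2 lists. The next were at chromosome 8, 69765778, chromosome 1, 38156290, chromosome 2, 35523799, and chromosome 17, 72754606, in 6, 8, 4 and 3 lists. These 5 DMSO summits lay 1048 to 2415 bp from the nearest E2 summit. At equal length, where the DMSO list stays whole with its weakest calls, 57.5% (56.4 to 58.6) of E2 summits were matched by DMSO.

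The reference antagonists were compared with E2 to ask how much of the agonist-bound set each of them also showed. With Tamoxifen, 28 of the 30 estrogen target genes had a summit (93.3%, 77.9 to 99.2), and 23 genes had fewer summits than with E2. GREB1 had 11 summits against 15 with E2, CCND1, which encodes cyclin D1, had 8 against 12, IGF1R had 10 against 22 and MYC had 1 against 5. XBP1, a transcription factor gene of luminal cells, was the 1 target gene with more summits with Tamoxifen, 7 against 5. At equal length, Tamoxifen had more summits than E2 at 9 target genes and fewer at 8: IGF1R had 7 Tamoxifen against 4 E2 summits, GREB1 7 and 7, CCND1 4 and 5, MYC 0 and 0, and XBP1 6 and 4. The density in the target windows was 11.6 per 1000 summits (9.72 to 13.8) with Tamoxifen.

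With Fulvestrant, the list was the longest of the 10, and 29 of the 30 target genes had a summit (96.7%, 82.8 to 99.9). GREB1 had 7 Fulvestrant summits against 15 with E2, the transcription factor gene MYB had 5 against 9, and EGR3 had 1 against 5. The 7 GREB1 sites counted above as present with E2 and absent with DMSO were all absent from the Fulvestrant list. Target genes with more Fulvestrant than E2 summits were KRT13 (9 against 5), CA12 (9 against 8), XBP1 (6 against 5), CELSR2 (4 against 3) and AREG (1 against 0). At equal length Fulvestrant had more summits than E2 at 5 target genes and fewer at 15. GREB1 then had 5 Fulvestrant against 7 E2 summits, MYB 3 and 4, EGR3 1 and 3, KRT13 1 and 3, CA12 3 and 5, XBP1 6 and 4, CELSR2 3 and 3, and AREG 0 and 0. The density in the target windows was 7.95 per 1000 summits (6.74 to 9.31), below the interval of 9.72 to 12.9 for E2. At equal length it was 9.62 (7.52 to 12.1) against 12.5 (10.1 to 15.3), and these intervals overlapped.

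At the luminal factor genes the Fulvestrant list was above the E2 list at 4 of 10 genes and below it at 5, and at equal length above it at 5 and below it at 1. FOXA1, a pioneer factor that opens chromatin for ERα, had 9 Fulvestrant, 7 E2 and 2 DMSO summits. SPDEF, an epithelial transcription factor gene, had 8, 3 and 1, and TRPS1 had 0, 2 and 1. ESR1, the gene of ERα itself, had 5 Fulvestrant, 8 E2, 8 Tamoxifen and 4 DMSO summits. At equal length the Fulvestrant, E2 and DMSO numbers were 2, 3 and 2 at FOXA1, 2, 2 and 1 at SPDEF and 0, 0 and 1 at TRPS1, and ESR1 had 3 Fulvestrant, 3 E2, 4 Tamoxifen and 4 DMSO summits.

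Over the genome, 46.2% (45.5 to 47.0) of E2 summits had a Tamoxifen summit and 65.4% (64.7 to 66.1) had a Fulvestrant summit. Of the Tamoxifen summits, 73.4% (72.6 to 74.2) had an E2 summit, and of the Fulvestrant summits, 59.3% (58.6 to 60.02) had one. At equal length the overlap with E2 was 66.4% (65.3 to 67.4) for Tamoxifen and 68.2% (67.1 to 69.3) for Fulvestrant. This order turned in shorter lists: among the 2000 highest-scoring summits it was 74.6% for Tamoxifen and 70.85% for Fulvestrant. The 5 highest-scoring E2 summits with no Tamoxifen summit within 1000 bp were at chromosome 16, 21524053, chromosome 4, 6282236, chromosome 11, 72903557, chromosome 6, 149401506, and chromosome 17, 39949628, with the nearest Tamoxifen summit 1015, 10783, 1466, 237617 and 6477 bp away. For Fulvestrant they were at chromosome 1, 38158019, chromosome 1, 202077593, chromosome 16, 88827341, chromosome 21, 41712503, and chromosome 15, 93188957, with the nearest Fulvestrant summit 1745, 1079, 2790, 15887 and 1177 bp away. The 5 highest-scoring Tamoxifen summits with no E2 summit within 1000 bp were at chromosome 17, 72754592, chromosome 8, 69765762, chromosome 1, 10812639, chromosome 16, 21523038, and chromosome 2, 35523796, the first at rank 231 of the Tamoxifen list, with the nearest E2 summit 2429, 1064, 1286, 1015 and 1143 bp away. For Fulvestrant they were at chromosome 1, 38156274, chromosome 16, 4666624, chromosome 18, 20839727, chromosome 6, 27209375, and chromosome 2, 1349086, the first at rank 837 of the Fulvestrant list, with the nearest 1745, 1711, 1812, 10296 and 2505 bp away.

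H3B-5942, Rad1901, 800 and H3B-6545 were set beside E2 and DMSO in the same way. With H3B-5942, 29 of the 30 target genes had a summit, 18 had fewer summits than with E2 and 5 had more. GREB1 had 15 H3B-5942 summits, as with E2, and MYC had 4 against 5. IGF1R had 11 against 22, CCND1 had 8 against 12 and CA12 had 10 against 8. At equal length, 11 target genes had more H3B-5942 than E2 summits and 10 had fewer; IGF1R had 6 against 4, GREB1 8 against 7, MYC 1 against 0, CCND1 3 against 5 and CA12 5 against 5. With H3B-6545, 16 target genes had fewer summits than with E2 and 8 had more, and at equal length 7 had fewer, 8 had more and 15 had as many. GREB1 had 16 H3B-6545 summits, and progesterone receptor, PGR, a classical estrogen-induced gene, had 4 against 3 with E2; at equal length GREB1 had 8 against 7 and PGR 2 against 1. Rad1901 and 800 each had summits at 28 of the 30 target genes, and GREB1 had 15 and 13 (7 and 8 at equal length). The density in the target windows was 11.1 per 1000 (9.43 to 12.9) for H3B-5942, 10.5 (9.03 to 12.2) for H3B-6545, 10.6 (9.02 to 12.3) for Rad1901 and 10.0 (8.48 to 11.7) for 800.

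**Figure D3:**
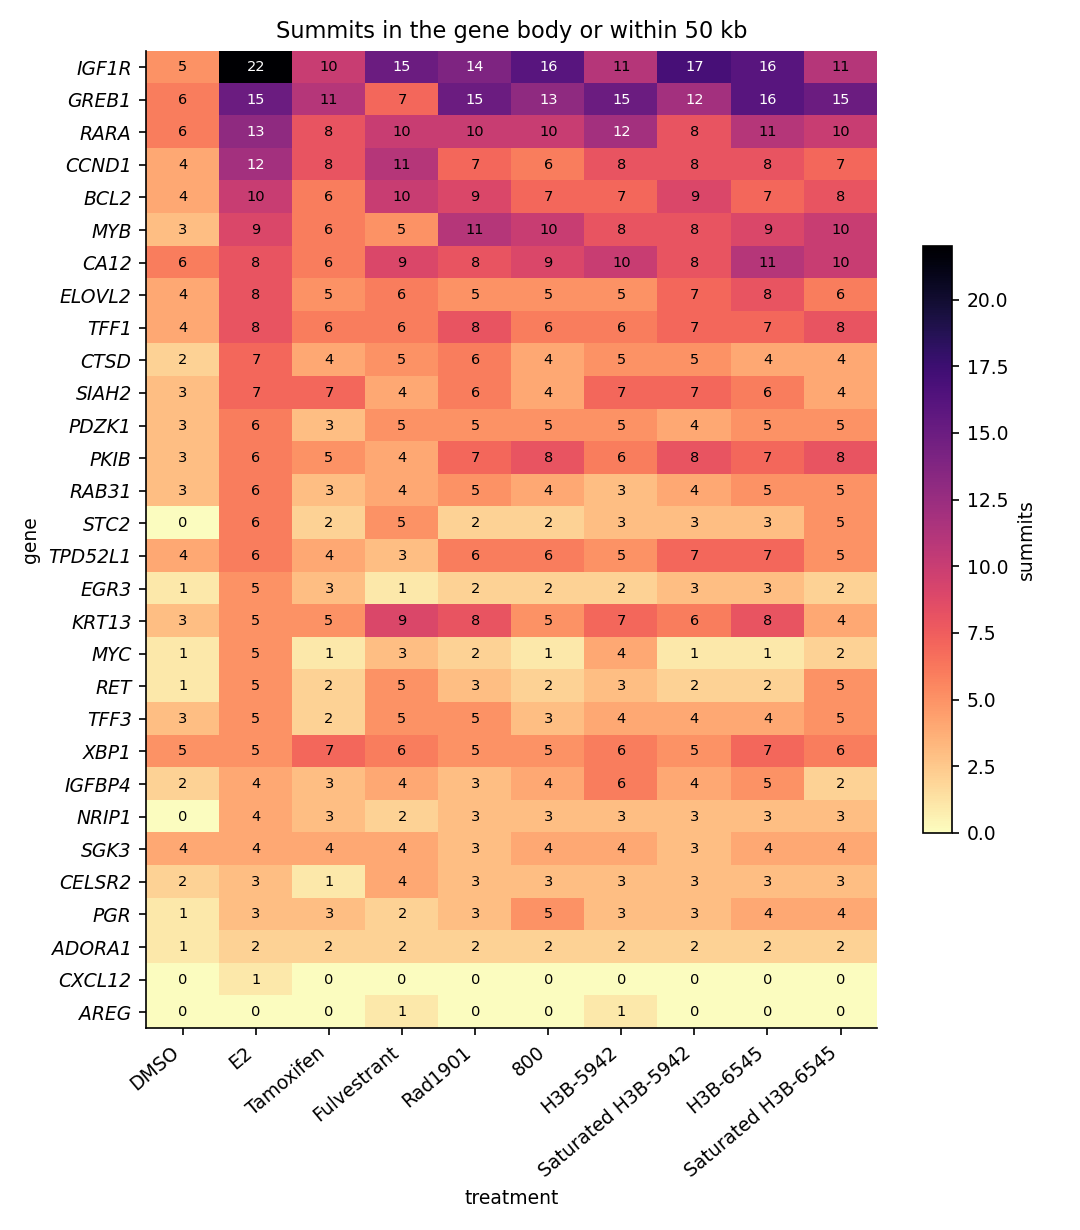
Each cell gives the number of ERα summits in the gene body or within 50 kb of 1 of 30 estrogen target genes (vertical axis, ordered by the E2 number) in the list of each treatment (horizontal axis); darker cells hold more. The numbers are those of the full lists, which differ in length; IGF1R had 22 E2 and 5 DMSO summits, and GREB1 had 7 Fulvestrant summits against 11 to 16 in the other treated lists.

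Of the E2 summits, 57.3% (56.6 to 58.1) had an H3B-5942 summit, 63.7% (62.9 to 64.4) an H3B-6545 summit, 63.6% (62.9 to 64.3) a Rad1901 summit and 58.1% (57.3 to 58.8) an 800 summit. Each share was above that of Tamoxifen and below that of Fulvestrant. At equal length, Rad1901 was the list closest to E2, with 76.1% of summits matched, and H3B-6545 followed with 72.4%, H3B-5942 with 69.5% and 800 with 69.0%, all above the 68.2% of Fulvestrant. Of the DMSO summits, 80.1% (79.2 to 81.0) had an H3B-5942 summit and 80.02% (79.1 to 80.9) an H3B-6545 summit, against 67.9% (66.9 to 69.0) for Tamoxifen and 78.7% (77.8 to 79.6) for Fulvestrant. Summits with no DMSO match made up 59.4% (58.6 to 60.2) of the H3B-5942 list, 54.4% (53.5 to 55.4) of the Tamoxifen list and 69.8% (69.2 to 70.5) of the Fulvestrant list. These shares depend on the list lengths. At equal length the overlap with DMSO was 64.2% for H3B-5942, 61.9% for H3B-6545, 58.4% (57.3 to 59.5) for Tamoxifen and 56.7% (55.5 to 57.8) for Fulvestrant. Tamoxifen was then above Fulvestrant, with overlapping intervals, and H3B-5942 had a smaller unmatched share than Tamoxifen. The DMSO list was whole in this comparison, weakest calls included, and the other lists were not. Among the 2000 highest-scoring summits of each list, the overlap with DMSO was 75.1% for H3B-5942 and 70.65% for H3B-6545. It was 69.55% for Tamoxifen and 63.5% for Fulvestrant, so the order was the same.

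**Figure D4:**
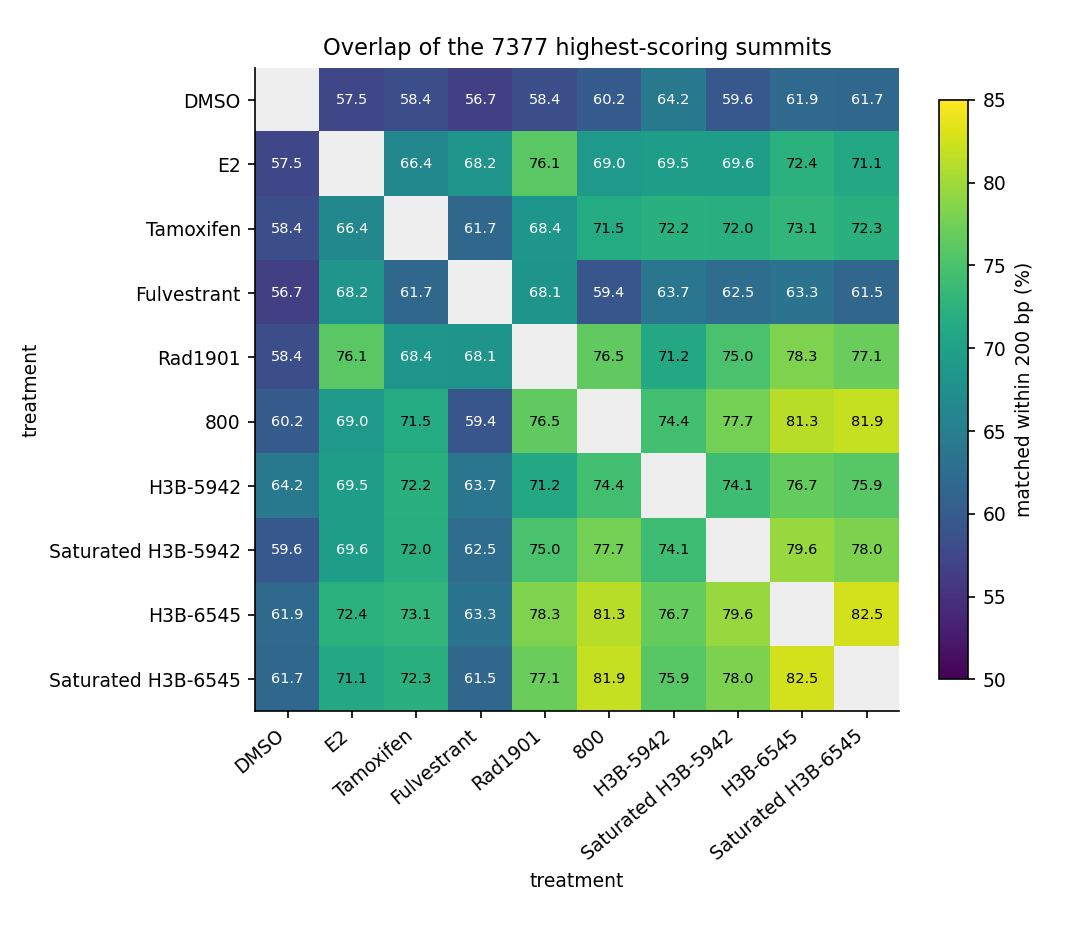
Each cell gives the percentage of the 7377 highest-scoring summits of 1 treatment that were matched within 200 bp by those of the other, for all 45 pairs of lists (both axes are treatments; yellow is higher). H3B-6545 and Saturated H3B-6545 overlapped most, at 82.5%, and DMSO and Fulvestrant least, at 56.7%. The DMSO list is whole, weakest calls included, and the other lists are cut to their highest-scoring summits.

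Each H3B compound was compared with its saturated form. At GATA3, a luminal transcription factor gene, H3B-5942 had 7 summits and Saturated H3B-5942 had 1, while H3B-6545 had 6 and Saturated H3B-6545 had 3. At equal length each of these 4 lists had 1 GATA3 summit. GREB1 had 15 and 12 summits in the H3B-5942 pair and 16 and 15 in the H3B-6545 pair. IGF1R had 11 H3B-5942 and 17 Saturated H3B-5942 summits, and had 16 and 11 in the H3B-6545 pair. At equal length IGF1R had 6 and 3 in the H3B-5942 pair and 7 and 7 in the H3B-6545 pair, and GREB1 had 8 and 10, and 8 and 7. The labels give no doses, so these are values side by side and not a comparison at matched dose.

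At the E2 summits, the matched share of H3B-6545 exceeded that of its saturated form by 5.07 percentage points (4.48 to 5.64), with 1884 sites matched by H3B-6545 alone and 999 by the saturated form alone. At equal length the difference was 1.25 points (0.433 to 2.05). For H3B-5942 the difference was 1.15 points (0.462 to 1.84), and it was -0.149 points (-1.12 to 0.821) at equal length and -1.44 points (-2.30 to -0.584) among summits with a score of at least 10. The H3B-5942 share minus the H3B-6545 share was -6.32 points (-6.99 to -5.65), and -2.89 points (-3.79 to -1.97) at equal length. Between the saturated forms the difference was -2.41 points (-3.05 to -1.76), and -1.49 points (-2.41 to -0.565) at equal length. At the DMSO summits the order was another: the H3B-5942 share minus that of its saturated form was 4.23 points (3.33 to 5.11), and 4.60 points (3.67 to 5.50) at equal length, and minus that of H3B-6545 it was 0.0678 points (-0.797 to 0.932), and 2.29 points (1.37 to 3.20) at equal length. The H3B-6545 share minus that of its saturated form was 2.68 points (1.95 to 3.40) there, and 0.230 points (-0.523 to 0.982) at equal length.

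The H3B-6545 pair overlapped by 82.5% (81.7 to 83.4) at equal length and the H3B-5942 pair by 74.1% (73.1 to 75.1). H3B-5942 overlapped more with H3B-6545 (76.7%) than with its own saturated form. H3B-6545 was also the closest list of Tamoxifen, Rad1901 and Saturated H3B-5942. The 800 list overlapped Saturated H3B-6545 by 81.9% (81.0 to 82.7) and H3B-6545 by 81.3% (80.3 to 82.1). Both intervals overlapped that of the H3B-6545 pair, so a high overlap was not particular to a compound and its saturated form. The highest-scoring H3B-5942 summit with no Saturated H3B-5942 summit within 1000 bp was at chromosome 8, 69766861, rank 608. In the other direction it was at chromosome 8, 69765773, rank 342. Both positions belong to 1 stretch of chromosome 8 and lie just beyond the limit of 1000 bp. For H3B-6545 it was at chromosome 2, 1348877, rank 3385, and for Saturated H3B-6545 at chromosome 3, 126792914, rank 2683, with the nearest summit of the other list 2305 and 1039 bp away.

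Across all lists, summits fell into 35932 union sites. Of these, 4139 (11.5%) were in all 10 lists, 12771 (35.5%) were in 1 list, and 1388 were in all 9 treated lists and not in DMSO. Among the full lists, the Fulvestrant list had the most sites of its own, 3927 (20.4% of its sites, 19.9 to 21.02). The E2 list had 1976 (11.4%, 10.9 to 11.8), the H3B-5942 list 1214 (8.37%, 7.92 to 8.83) and the DMSO list 400 (5.43%, 4.92 to 5.97). Such sites were also counted if their summit was among the 7377 highest-scoring of its own list, with the other lists kept at full length. DMSO, whose whole list this is, had the most, 400 (361.8 to 441.2), against 198 (171.4 to 227.6) for Fulvestrant, 194 for Tamoxifen, 65 for H3B-5942 and 64 for E2. The summit with the highest score in the E2 list, at chromosome 19, 4791590, was in all 10 lists and also ranked first in the DMSO list. All 3 highest-scoring summits of every list were at sites present in all 10 lists.

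The other gene lists were counted in the same way. All 10 luminal factor genes had a summit in the E2 and DMSO lists (100%, 69.2 to 100), and 9 had one in the Fulvestrant list. Of the 6 basal or mesenchymal genes, 2 had an E2 summit (33.3%, 4.33 to 77.7), and KRT5 and CDH2 had 0 in every list. Of the 12 genes of other lineages, 8 had an E2 summit (66.7%, 34.9 to 90.1) and 7 a DMSO summit. The liver gene ALB and the heart gene MYH6 had 0 in every list, while the rod photoreceptor gene RHO had 8 E2 and 4 DMSO summits (6 and 4 at equal length). Of the 6 housekeeping genes, 3 had a summit in the E2 list and 3 in the DMSO list, with an interval of 11.8 to 88.2% for each. The density of E2 summits in these windows was 3.21 per 1000 summits (2.42 to 4.16) for the luminal factors, 1.55 (1.02 to 2.25) for other lineages, 0.458 (0.198 to 0.903) for housekeeping genes and 0.172 (0.0354 to 0.502) for basal or mesenchymal genes. These values are not divided by the number of genes or the window length, so they do not compare the gene lists with each other. The median number of E2 summits per gene was 6 for the target genes and 5.5 for the luminal factors. It was 1.5 for other lineages, 1 for housekeeping genes and 0 for basal or mesenchymal genes. At equal length these E2 medians were 3 for the target genes, 2 for the luminal factors and 0.5 for other lineages. They were then 0 for housekeeping genes and 0 for basal or mesenchymal genes. The medians are not corrected for window length either. Chromosome 19 held 6.34% of DMSO summits (5.80 to 6.92) and 5.16% of E2 summits (4.84 to 5.50); at equal length the E2 share was 5.82%, inside the DMSO interval.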

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

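All alternatives but 1 were fixed before the data were examined; removing the 5 bins of 50 kb whose summit number differed most between lists was chosen after the lists were seen. The DMSO list gave the lowest share of E2 summits and Tamoxifen the second-lowest at each match distance, with a score of at least 10 and at an equal length of 7377 summits. In equal-length lists of 2000 and 5000 summits DMSO stayed the lowest. Fulvestrant was then the second-lowest, at 70.85 and 69.5%, below Tamoxifen at 74.6 and 70.3%. The list with the highest share did depend on the setting: it was Fulvestrant at full length at each match distance, Rad1901 (71.7%) with a score of at least 10, and Rad1901 (76.1%) at equal length. The numbers of estrogen target genes with a summit in the 5 lists of DMSO, E2, Tamoxifen, Fulvestrant and H3B-5942 stayed within 1.5 times of the main numbers in every alternative, which says little, since 26 to 29 of 30 is near the ceiling; the E2 summits at single genes fell far more at equal length, from 22 to 4 at IGF1R and from 6 to 0 at STC2. Among 597 values under alternatives, for 165 results, 256 stayed inside the 95% interval of the main share or within 1.5 times of the main count, and 2 changed sign. The other 339 moved out of that bound, 275 of them by at most 1.5 times and 64 by more. Counting the summits of 1 peak once changed nothing, since no peak had more than 1 named summit. Keeping chromosomes 1 to 22 and X only moved no number of summits by 1.5 times. Depth is unknown, so it is not known which calls a deeper library would add. Motif shares, the place of summits relative to genes and the random gene lists were not run. Where the construction of the alternative does not show it (a wider distance matches more, a shorter list holds less), the cause was not tested.

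With a score of at least 10, the lists held 4202 summits for DMSO, 10314 for E2, 5719 for Tamoxifen, 10679 for Fulvestrant and 7677 for H3B-5942. The share of E2 summits matched was then 34.6% by DMSO, 68.1% by Fulvestrant and 58.3% by H3B-5942. The share of DMSO summits matched was 84.96% by E2, 73.6% by Tamoxifen, 84.4% by Fulvestrant and 86.03% by H3B-5942, and the summits without a DMSO match made up 65.4, 45.9, 66.8 and 52.9% of these lists. With every list filtered in this way, sites in all 10 lists numbered 2653, those in the E2 list alone 954 and those in the Fulvestrant list alone 1976. The H3B-5942 difference from its saturated form at E2 summits was -1.44 points.

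At equal length, the share of E2 summits matched was 57.5% by DMSO, 66.4% by Tamoxifen, 68.2% by Fulvestrant and 69.5% by H3B-5942. The share of DMSO summits matched was 57.5% by E2, 58.4% by Tamoxifen, 56.7% by Fulvestrant and 64.2% by H3B-5942. The difference from the saturated form was -0.149 points for H3B-5942 and 1.25 points for H3B-6545.

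With a match distance of 100 bp, the share of E2 summits matched was 29.998% by DMSO, 40.8% by Tamoxifen, 58.2% by Fulvestrant and 50.6% by H3B-5942. The share of DMSO summits matched was 70.99% by E2, 61.5% by Tamoxifen, 70.95% by Fulvestrant and 72.9% by H3B-5942, and the summits without a DMSO match made up 70.002, 58.8, 72.8 and 63.02% of these lists. The difference from the saturated form was 0.195 points for H3B-5942 and 4.08 points for H3B-6545. The equal-length overlap with E2 was 62.8% for Tamoxifen, 65.7% for Fulvestrant and 66.2% for H3B-5942, and it was 70.5% within the H3B-5942 pair and 80.3% within the H3B-6545 pair.

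With a match distance of 500 bp, the share of E2 summits matched was 35.1% by DMSO, 50.1% by Tamoxifen, 70.97% by Fulvestrant and 62.1% by H3B-5942. The share of DMSO summits matched was 82.4% by E2, 71.99% by Tamoxifen, 83.99% by Fulvestrant and 84.04% by H3B-5942, and the summits without a DMSO match made up 64.9, 51.2, 67.5 and 56.6% of these lists. The equal-length overlap with E2 was 68.1% for Tamoxifen, 69.6% for Fulvestrant and 70.8% for H3B-5942, and it was 76.5% and 83.6% within the H3B-5942 and H3B-6545 pairs.

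Among the 2000 highest-scoring summits of each list, the overlap with E2 was 74.6% for Tamoxifen, 70.85% for Fulvestrant and 73.3% for H3B-5942, and it was 81.3% and 88.7% within the H3B-5942 and H3B-6545 pairs. Among the 5000 highest-scoring, it was 70.3% for Tamoxifen, 69.5% for Fulvestrant and 70.7% for H3B-5942, and 77.2% and 84.96% within the pairs. Tamoxifen was thus above Fulvestrant in overlap with E2 in these shorter lists and below it at 7377 summits. Without the 5 varying bins, sites in the Fulvestrant list alone numbered 3895 and those in the E2 list alone 1971.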

Other observations

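All tests and counts here were chosen after the lists were seen, except the tests of summit splitting for both patterns that use it and the test of a lower DMSO yield, which were set before their results were seen.

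GREB1 sites that were in all the other treated lists and absent from DMSO and Fulvestrant prompted a count of such sites over the genome. There were 432 (392.2 to 474.7), and 11 of them (2.55%, 1.28 to 4.51) were in the windows of 8 estrogen target genes. Of all 35932 union sites, 320 (0.891%, 0.796 to 0.993) were in windows of estrogen target genes. GREB1 held 3 of the 11, the sites that prompted the count, so the share is no test of whether such sites lie at target genes. NRIP1 held 2, at chromosome 21, 16375849 to 16375948 and 16437832 to 16438069. TFF1 (chromosome 21, 43811014 to 43811055), PGR (chromosome 11, 100870614 to 100870687), CCND1 (chromosome 11, 69418944 to 69419148), CTSD, TPD52L1 and PKIB held 1 each. The matching set absent from DMSO and Tamoxifen held 445 sites (404.6 to 488.3), with 2 (0.449%, 0.0545 to 1.61) in such windows, and the intervals of the shares overlapped. Another 1388 sites were in all 9 treated lists and not in DMSO.

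A few short regions held many summits in some lists and next to none in others; the 5 bins of 50 kb on chromosomes 1 to 22 and X with the largest spread between lists are given here. The first lies at a tandem repeat, and the others were not examined for repeats. Whether reads that map to several places set these counts was not tested for any of the 5 bins, since that needs the reads. At chromosome 1, 228750001 to 228800000, on the long arm where the 5S ribosomal RNA gene array lies, there were 31 Fulvestrant, 28 Tamoxifen, 23 E2 and 16 H3B-5942 summits. DMSO, Rad1901 and 800 had 0 there, Saturated H3B-5942 had 1, and the H3B-6545 pair had 4 and 3. The median distance between neighbouring Fulvestrant summits in this bin was 1010 bp. At chromosome X, 114950001 to 115000000, Tamoxifen had 28, Fulvestrant 23, E2 17 and DMSO 0, and at chromosome 10, 135450001 to 135500000, Fulvestrant had 18, E2 and Tamoxifen 13 each and DMSO, Rad1901 and 800 had 1 each. At chromosome 1, 161400001 to 161450000, Fulvestrant had 16, Tamoxifen 10 and DMSO 0. At chromosome 19, 36750001 to 36800000, Fulvestrant had 16, Tamoxifen 4, Saturated H3B-5942 1 and the other lists 0. Together these bins held 104 summits of the Fulvestrant list, 83 of Tamoxifen, 56 of E2, 26 of H3B-5942, 7 of Rad1901, 7 of 800 and 1 of DMSO, which was 0.754% of the Tamoxifen list and 0.0136% of the DMSO list. At chromosome 17, 59 to 60 Mb, the DMSO list had the most summits of any list, 49 against 28 to 39, although it was the shortest. MCF7 cells have amplified regions, and whether copy number set these counts was not tested, so they do not show binding particular to vehicle.

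The Fulvestrant list held 3927 sites found in no other list. More sensitive peak calling in that library stays open. The sites it lacked were counted: 114 sites of the other 9 lists (94.0 to 136.9) had no Fulvestrant summit within 1000 bp. This number ran from 5 (1.62 to 11.7) for H3B-6545 to 58 (44.0 to 75.0) for E2 in 7 shorter lists. It was 277 for Tamoxifen and 1354 for DMSO, the shortest. A library with more sensitive calling can also lack some shared sites, so this count does not decide the origin of the 3927 sites. Splitting of a broad peak within 1000 bp of another list's summit is argued against for most of these sites. Only 30.9% (29.4 to 32.4) lay that close. For the sites of 1 list elsewhere this share ran from 27.1% for 800 to 58.4% for H3B-5942. Splitting over longer distances was not tested, nor was splitting of broad regions that only the Fulvestrant list held. Calls close to the score threshold stay open: 3232 of these sites had a score below 10. Another 695 (644.3 to 748.6) had at least 10, against 260 (229.4 to 293.6) for E2, but scores of libraries of unknown depth may differ in scale. Sites of 1 full list whose summit was among the 7377 highest-scoring of that list were also counted. They numbered 198 (171.4 to 227.6) for Fulvestrant, 194 (167.7 to 223.3) for Tamoxifen, 64 (49.3 to 81.7) for E2 and 400 (361.8 to 441.2) for DMSO, whose whole list this is. What also stays open, as a hypothesis, is that Fulvestrant itself may have moved the receptor to other sites at 45 min, or that some other property of this 1 library set it apart; neither was tested.

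The H3B-5942 pair overlapped less than the H3B-6545 pair at equal length, by 8.45 points (7.12 to 9.77). Splitting of broad peaks, which the many close H3B-5942 summits could produce, stays open. The gap was 7.75 points (6.41 to 9.09) after keeping 1 summit per 1000 bp. The summit kept in a broad region need not be the same one in each list, so this test cannot decide the question. Whether the H3B-5942 library stands apart in general was not decided: its overlap was lower than that of its saturated form with 5 of the 8 other lists and higher with 3, DMSO (64.2 against 59.6%), Fulvestrant (63.7 against 62.5%) and Tamoxifen (72.2 against 72.01%). A real difference between H3B-5942 and its saturated form stays open and was not tested, since each has 1 library and no stated dose.

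The DMSO list was the shortest, and a lower yield of the same sites is a candidate explanation that these data leave open. The planned test decided nothing: among the 1000 highest-scoring E2 summits, 97.6% had a DMSO summit within 1000 bp, but over all pairs of lists this share was never below 95.5%. DMSO was also the list least like E2 among the 2000 highest-scoring summits (64.7%, against 70.85% for Fulvestrant, the next, and 80.4% for Rad1901, the highest). A lower yield may come from less efficient immunoprecipitation, lower depth or less receptor on chromatin without ligand. The biological explanation, that ligand added sites, stays open and untested, for example at NRIP1 with 3 E2 and 0 DMSO summits at equal length.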
